A study of Mus musculus with 39 samples.

How the data were processed

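RNA was measured in left ventricular tissue of 39 mouse hearts in 11 labelled groups. Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with a stranded TruSeq mRNA kit. Per the submitters' processing notes, reads were aligned to the mouse genome mm10 with STAR 2.7.3a and assigned to genes with featureCounts of Subread 2.0.0. The deposited values are whole-number counts per gene and library, as the authors made them. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap or have antisense partners are uncertain, as are near-identical paralogs.

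The table held 38293 genes, and all of its columns were matched to a sample label. Symbols and positions came from GENCODE vM21 (GRCm38), which named 36345 of the gene IDs, and unnamed IDs took 0.13% of counts. Depth ran from 9.4 M to 19.3 M counts per library. Replicates were checked in pairs with a chi-square statistic per gene over genes with at least 50 counts in the pair. On the Y-linked genes 39 of 39 libraries stood on the male side.

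Groups were taken from the labels. Homozygous and wild type hearts were compared at 3, 5 and 8 weeks, heterozygous with wild type and homozygous with heterozygous hearts at 8 weeks, and ischemia-reperfusion and infarction each with the 4 pooled shams. Each fit held the groups of 1 age, or the surgery set. Counts were normalized with TMM, low counts were filtered with filterByExpr, and genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference between 2 effects was tested as an interaction in 1 fit of all 39 libraries. CPM are counts scaled to each library's total, with the SD between libraries. Fold changes come from the fit with TMM scaling, so they can differ from the ratio of 2 CPM means. Their standard error was taken as the absolute log2 fold change divided by the square root of the test's F statistic.

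Gene lists, 23 by function and 17 by cell type, were written from general knowledge before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives, apart from those stated otherwise. They were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts per list come from the adjustment over all genes, and beside them counts adjusted over the list alone. The genes named in the text follow a rule. It takes 10 marker genes of cardiac stress, calcium handling and matrix, the 6 largest rises and 6 largest falls with at least 5 CPM in a group and no overlap between groups, and from each list with at least 3 passing genes those with the smallest p and 1 that moved the other way. For differences between effects it takes the 5 largest each way. A gene with a group at 0 counts gets a bound from a floor of 3 counts over the group.

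Agreement between comparisons was given as genes called in both, beside the number expected of independent lists, and as the correlation and covariance of fold changes. For comparisons that share controls, unchanged groups were simulated against the same controls in 20 simulations. The scripts were tested on simulated data with known changes. Other splits of the same libraries into groups of the same size were fitted in the same way. Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and library size scaling, other filters, a robust dispersion, a fold change threshold, other sets of libraries in the fit, age-matched shams, a block on replicate number, and each library left out in turn. A covariate for sex was left out because all libraries stood on the same side.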

Results

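RNA sequencing of left ventricular tissue covered 39 mouse hearts in 2 experiments on C57BL6/J mice. In the first set, hearts carried R14del, a deletion of the codon for arginine 14 of Pln, the gene for phospholamban, a small membrane protein that restrains the calcium pump of the sarcoplasmic reticulum. Wild type and homozygous hearts were sampled at 3 weeks (n = 4 each) and 5 weeks (n = 4 each), and at 8 weeks wild type (n = 3), heterozygous (n = 4) and homozygous (n = 4) hearts were sampled. In the second set, male mice aged 12 weeks at surgery were studied 3 days after ischemia-reperfusion, in which a coronary artery is closed for a time and reopened (n = 4), or 8 weeks after permanent closure, called infarction here (n = 4). The tissue came from myocardium away from the infarct. Sham-operated hearts were pooled as 1 control group of 4, with 2 hearts aged 12 weeks and 2 aged 20 weeks. The deposited counts summed to between 9.4 M and 19.3 M per library. They ran from 9.78 M to 12 M at 5 weeks, from 13.1 M to 19.3 M at the other ages of the mutant set, and from 9.4 M to 15.7 M in the surgery set. Among 57 pairs of replicates no pair held identical counts, and the chi-square statistic per gene lay between 4.03 and 97.4, so that each library was counted as 1 sample. The labels name separate samples and do not number animals, so p-values measure the spread between these samples.

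Pln itself was examined first in every group. The gene (ENSMUSG00000038583) lies on the plus strand of chromosome 10 from 53337667 to 53345987 in GRCm38. Reads counted per gene do not show the deletion, so its level checks no genotype label. Of the other markers followed, Nppa lies on chromosome 4 from 148000722 to 148002079, Nppb on 4 from 147985788 to 147987205, Myh7 on 14 from 54970684 to 54994626, Myh6 on 14 from 54941921 to 54966927 and Acta1 on 8 from 123891769 to 123894751. Atp2a2 lies on 5 from 122453513 to 122502225, Col1a1 on 11 from 94936224 to 94953042, Col3a1 on 1 from 45311538 to 45349706 and Postn on 3 from 54361109 to 54391037. At 3 weeks Pln stood at 4410 ± 504 CPM (counts scaled to library total; mean ± SD, n = 4) in homozygous and 4065 ± 368 CPM in wild type hearts. At 5 weeks it fell by 0.79 ± 0.07 on the log2 scale (SE), from 5813 ± 138 to 3865 ± 192 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.37e-08). At 8 weeks it fell by 1.48 ± 0.15, from 4952 ± 241 CPM in wild type (n = 3) to 1980.3 ± 199 CPM in homozygous hearts (edgeR adjusted p = 5.6e-06), while heterozygous hearts held 4957 ± 637 CPM. In the surgery set sham hearts held 6665 ± 251 CPM. Pln fell by 0.42 ± 0.11 after ischemia-reperfusion (edgeR adjusted p = 0.0117) and by 0.48 ± 0.11 after infarction (edgeR adjusted p = 0.0143). The calls in the surgery set ended with the age-matched shams alone, and the call after ischemia-reperfusion also ended with scaling by library size (adjusted p = 0.136).

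**Figure D1:**
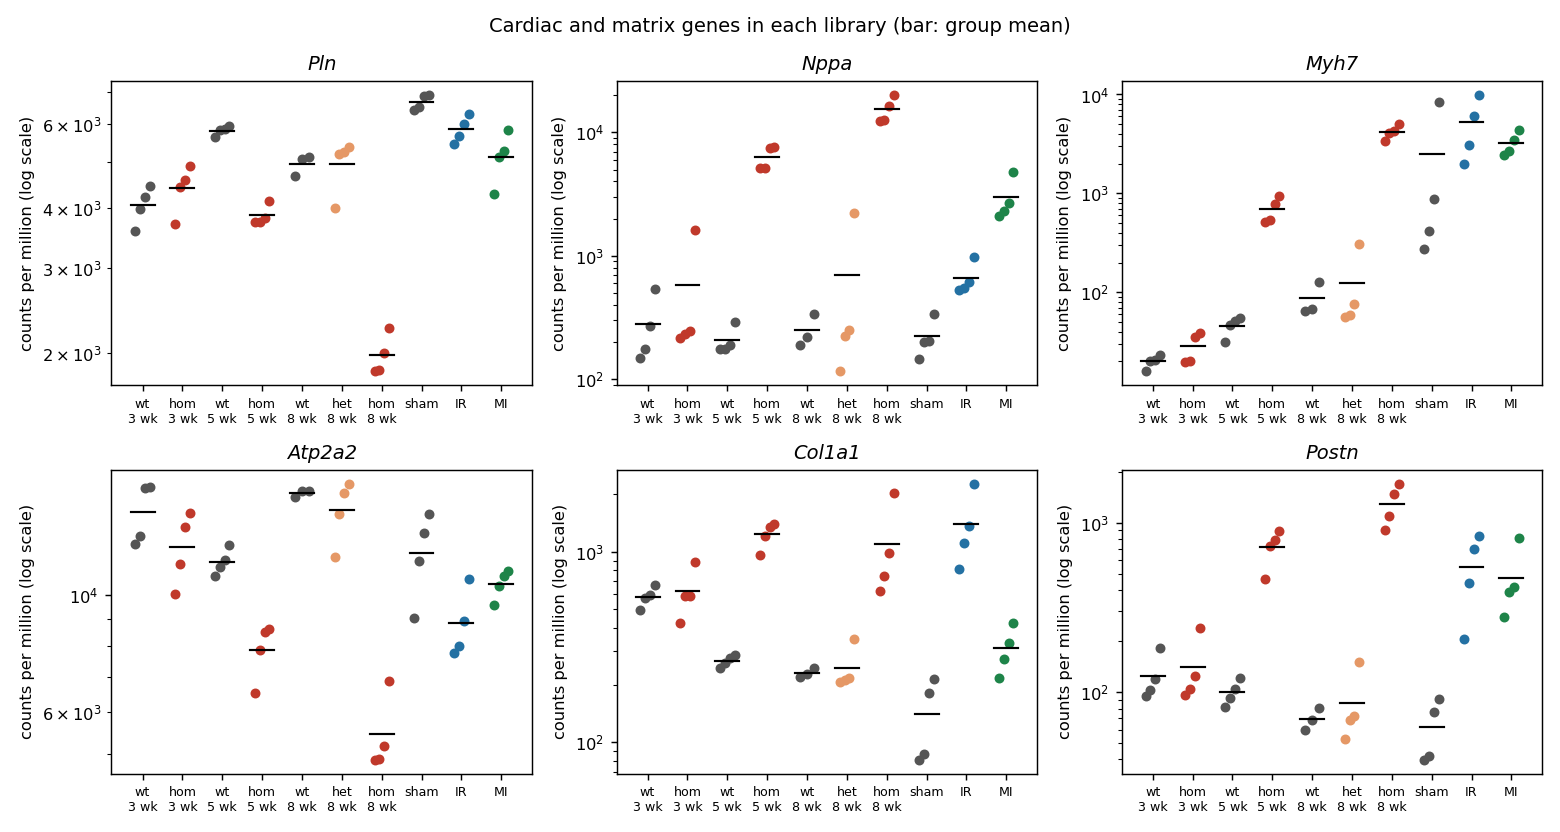
Level of Pln, Nppa, Myh7, Atp2a2, Col1a1 and Postn in CPM on a log axis, 1 point per library and a bar at each group's mean. Nppa averaged 6328 CPM in homozygous hearts at 5 weeks and 15401 CPM at 8 weeks, against 207 and 249 CPM in wild type hearts of those ages.

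At 3 weeks, the earliest age of the series, the edgeR test called no gene between homozygous and wild type hearts, while DESeq2 and 3 other alternatives called 4 to 112. Nppa, which encodes the atrial natriuretic peptide and is a marker of cardiac stress, stood at 578 ± 696 CPM (SD, n = 4) in homozygous and 281 ± 176 CPM in wild type hearts (edgeR adjusted p = 0.581). The homozygous spread came from replicate 3 at 1621 CPM, as the other 3 hearts held 214 to 246 CPM. Atp2a2, the gene of the calcium pump that phospholamban restrains, differed by a log2 change of -0.25 ± 0.14 (edgeR adjusted p = 0.512), and Myh7, the slow beta myosin heavy chain, by 0.48 ± 0.21 (edgeR adjusted p = 0.427). The edgeR test called 0 of 13427 genes, with 1515 at an unadjusted p under 0.05. DESeq2 called 112 and limma-voom 0. The count was 25 without the filter on low counts, 40 with all 39 libraries in the fit and 4 without homozygous replicate 2. In simulated data of this size the test recovered 47.8% of 1.5-fold, 86.6% of 2-fold and 92.4% of 4-fold changes. The simulated counts took the fitted dispersions as exact and genes as independent, so these shares do not give the power in the real libraries.

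Of 37 gene lists tested at 3 weeks with camera, 5 stood higher and 7 lower, and none of these calls held with an estimated correlation. The core clock genes of the Bmal1 phase had a median log2 change of 0.98 over 6 genes (camera adjusted p = 1.01e-10, adjusted p = 0.226 with an estimated correlation), and 5 of them rose when adjusted over the list alone. Immediate early genes, which respond to stimulation within minutes, had a median of 0.85 (camera adjusted p = 3.52e-08, adjusted p = 0.718 with an estimated correlation), with 5 of 16 higher adjusted over the list alone. Cell cycle genes had a median of -0.96 (camera adjusted p = 1.01e-10, adjusted p = 0.718 with an estimated correlation). Interferon-stimulated genes, part of the antiviral response, had a median of -0.52 (camera adjusted p = 1.26e-10, adjusted p = 0.718 with an estimated correlation), with 2 of 19 lower adjusted over the list alone. Fatty acid oxidation genes had a median of -0.16 (camera adjusted p = 3e-07, adjusted p = 0.718 with an estimated correlation), with 1 of 30 lower adjusted over the list alone. Adjusted in that way 4 of 18 heat shock genes were higher and 1 lower, in a list without a call (camera adjusted p = 0.106).

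At 5 weeks, homozygous hearts carried a broad change in expression. Genes of cardiac stress, extracellular matrix, the unfolded protein response and macrophages rose, and genes of fatty acid oxidation fell. Genes of the respiratory chain, ion channels and endothelial cells also fell, in lists whose calls were lost with an estimated correlation (adjusted p = 0.174, 0.119 and 0.0518). Nppa rose from 207 ± 54.9 to 6328 ± 1416 CPM (SD, n = 4 each), a 26.5-fold change. Col1a1, a chain of type I collagen, rose 4-fold from 267 ± 17.5 to 1235 ± 196 CPM. Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, fell by 1.15 ± 0.07 on the log2 scale. By the edgeR test 5821 of 13323 genes (43.7%) changed, 2969 up and 2852 down, and among them 932 rose and 269 fell by more than 1 on the log2 scale. With scaling by library size alone the median of all genes shifted by 0.21 on the log2 scale and the split became 5388 up and 1411 down.

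The genes with the largest rises at 5 weeks were led by Sprr1a, an epithelial barrier protein induced by cardiac stress, with a log2 change of 9.19 ± 0.36 (SE, edgeR adjusted p = 1.24e-12). Derl3, which takes part in the removal of misfolded proteins from the endoplasmic reticulum, rose by 7.80 ± 0.45 from 5 counts in the 4 wild type libraries. Spp1, which encodes the matrix protein osteopontin, rose by 6.72 ± 0.21, Il1rn, the antagonist of the interleukin 1 receptor, by 5.97 ± 0.37, Gdf15, a circulating stress cytokine, by 5.57 ± 0.32 and Serpina3n, a protease inhibitor of a multigene family, by 5.23 ± 0.18. The largest falls were those of Kcnv2, a modifier of potassium channels, at -2.57 ± 0.24, Mylk4, a myosin light chain kinase of the heart, at -2.48 ± 0.14, Acot1, an acyl-CoA thioesterase with a close paralog, at -2.43 ± 0.19, Scn4b, a sodium channel subunit, at -2.34 ± 0.16, and Lgals4 at -2.28 ± 0.10. Among these falls the highest edgeR adjusted p was 8.08e-08, for Kcnv2.

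Of 14 fetal and stress genes at 5 weeks 10 rose and none fell, with a median log2 change of 1.39 (camera adjusted p = 2.64e-18, adjusted p = 0.045 with an estimated correlation). Myh7 rose 13-fold from 46.1 ± 10.1 to 689 ± 201 CPM, Ankrd1, a stress-responsive nuclear and sarcomeric protein, rose by 2.69 ± 0.10 on the log2 scale and Nppb, the B-type natriuretic peptide, rose from 111 ± 33.5 to 514 ± 68.0 CPM. Myh6, the fast alpha myosin heavy chain of the adult mouse heart, fell by 0.79 ± 0.09 (edgeR adjusted p = 1.27e-06), and reads of these 2 similar genes can be split by the counting. Acta1, skeletal alpha actin, rose by 0.57 ± 0.12 (edgeR adjusted p = 0.000913), a call that ended with all 39 libraries in the fit (adjusted p = 0.476). Of 20 calcium handling genes 12 fell and 2 rose, and adjusted over the list alone 12 fell and 3 rose (camera adjusted p = 0.000604, adjusted p = 0.174 with an estimated correlation). Among them Atp2a2 fell by 0.76 ± 0.09, the ryanodine receptor Ryr2 by 0.80 ± 0.08 and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by 1.10 ± 0.10. Of 22 sarcomere and Z-disc genes 15 fell and 3 rose, and adjusted over the list alone 16 fell and 3 rose (camera adjusted p = 4.69e-05, adjusted p = 0.174 with an estimated correlation). Of 21 ion channel genes 15 fell and 2 rose, and adjusted over the list alone 16 fell and 2 rose (camera adjusted p = 4.16e-06, adjusted p = 0.119 with an estimated correlation). Kcnip2, a subunit of the transient outward potassium channel, fell by 1.64 ± 0.08.

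In energy metabolism at 5 weeks, 29 of 30 fatty acid oxidation genes fell and 1 rose, with a median of -0.93 (camera adjusted p = 4.31e-30, adjusted p = 0.045 with an estimated correlation). All 30 nuclear genes of oxidative phosphorylation fell, with a median of -0.56 (camera adjusted p = 6.74e-16, adjusted p = 0.174 with an estimated correlation), and all 7 mitochondrially encoded genes fell (camera adjusted p = 3.51e-06, adjusted p = 0.119 with an estimated correlation). All mitochondrially encoded genes together, also those outside the 7 tested, took 15 ± 0.641% of counts in homozygous and 20.4 ± 0.51% in wild type hearts. Of 25 genes of the TCA cycle and branched-chain amino acid breakdown 24 fell (camera adjusted p = 9.17e-18, adjusted p = 0.119 with an estimated correlation). Counts adjusted over the list alone equalled those over all genes for these 4 lists and for glycolysis. Of 20 glycolysis genes 7 rose and 7 fell (camera adjusted p = 0.84). Slc2a1, a glucose transporter, rose by 1.37 ± 0.11 on the log2 scale and Eno3, the muscle enolase, fell by 0.97 ± 0.09.

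Matrix and stress responses moved upward at 5 weeks. Of 32 extracellular matrix genes 30 rose and none fell, with a median of 1.51 (camera adjusted p = 9.65e-56, adjusted p = 0.045 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose 21.4-fold, and Postn, the matricellular protein periostin, rose 6.2-fold from 100.03 ± 16.9 to 718 ± 183 CPM. Of 21 genes of the unfolded protein response of the endoplasmic reticulum 20 rose, with a median of 1.08 (camera adjusted p = 2.21e-32, adjusted p = 0.045 with an estimated correlation), among them the chaperones and folding enzymes Creld2 at 2.47 ± 0.12, Pdia4 at 1.79 ± 0.08 and Hyou1 at 1.28 ± 0.06. Of 21 genes of the integrated stress response and one-carbon metabolism 17 rose (camera adjusted p = 4.57e-11, adjusted p = 0.045 with an estimated correlation), among them Mthfd2, a mitochondrial folate enzyme, at 3.07 ± 0.15. Of 18 genes of the oxidative stress response 10 rose and 2 fell, and adjusted over the list alone 10 rose and 3 fell (camera adjusted p = 2.29e-05, adjusted p = 0.174 with an estimated correlation). Hmox1, heme oxygenase, rose by 1.84 ± 0.10 and Sod2, the mitochondrial superoxide dismutase, fell by 0.61 ± 0.07. Of 18 heat shock genes 9 rose and 1 fell (camera adjusted p = 0.00299, adjusted p = 0.141 with an estimated correlation), led by the near-identical pair Hspa1a and Hspa1b, whose reads can be shared. Of 20 cytokine and acute inflammation genes 19 rose, with a median of 1.81 (camera adjusted p = 7.9e-15, adjusted p = 0.0725 with an estimated correlation), among them Ccl2, which recruits monocytes, at 2.87 ± 0.18. Unless given separately, counts adjusted over the list alone equalled those over all genes.

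Markers of other cell types moved apart at 5 weeks. Of 16 macrophage markers 14 rose and 1 fell, with a median of 2.27 (camera adjusted p = 1.6e-47, adjusted p = 0.0324 with an estimated correlation). Lgals3, galectin 3, rose 32.3-fold and C1qa, a complement component made by macrophages, rose 3.76-fold. Of 12 fibroblast markers 10 rose (camera adjusted p = 2.1e-06, adjusted p = 0.0518 with an estimated correlation), and of 11 activated fibroblast markers 10 rose and 1 fell (camera adjusted p = 2.52e-08, adjusted p = 0.119 with an estimated correlation). All 12 endothelial markers fell, with a median of -0.70 (camera adjusted p = 1.54e-11, adjusted p = 0.0518 with an estimated correlation), among them Cdh5, the cadherin of endothelial junctions, at -1.01 ± 0.07. Of 11 smooth muscle and pericyte markers 9 fell (camera adjusted p = 0.000381, adjusted p = 0.0518 with an estimated correlation). Of 11 cardiomyocyte markers 7 fell and none rose, and adjusted over the list alone 7 fell and 2 rose (camera adjusted p = 0.00399, adjusted p = 0.202 with an estimated correlation). Ckm, muscle creatine kinase, fell by 1.16 ± 0.09 on the log2 scale.

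**Figure D2:**
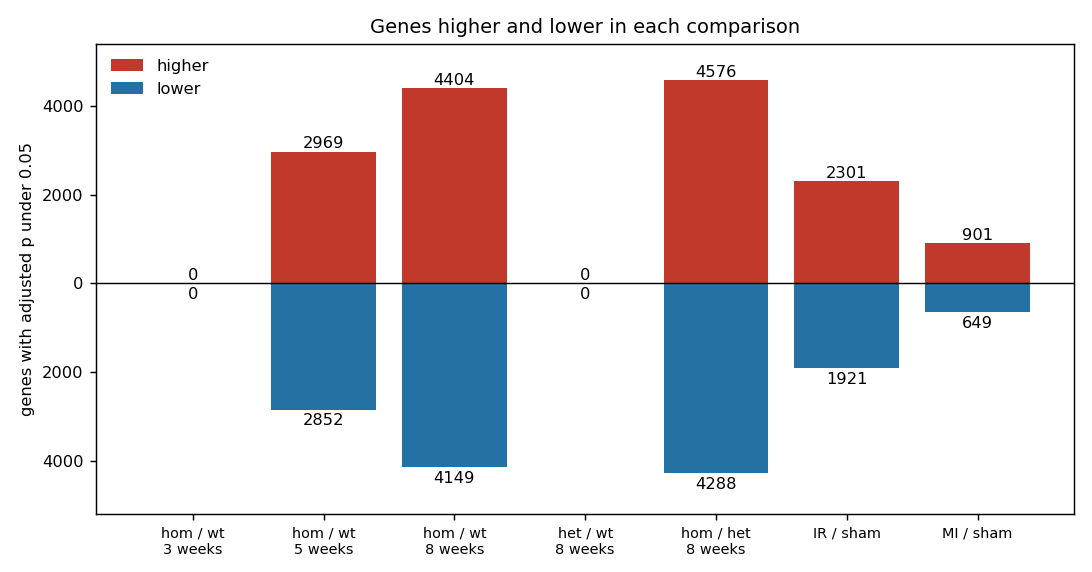
Number of genes higher and lower in each comparison at an adjusted p under 0.05 by the edgeR quasi-likelihood test. No gene passed in homozygous hearts at 3 weeks or in heterozygous hearts at 8 weeks, and 8553 passed in homozygous hearts at 8 weeks.

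At 8 weeks, the last age of the mutant set, homozygous hearts differed from wild type at most of the genes tested. Nppa reached 15401 ± 3717 CPM (SD, n = 4) against 249 ± 77.4 CPM (n = 3), a log2 change of 5.78 ± 0.98 (edgeR adjusted p = 0.000249). Myh7 rose 43-fold from 87.0 ± 35.7 to 4201 ± 700.1 CPM and Postn rose 16.5-fold from 69.6 ± 10.1 to 1295 ± 360.4 CPM. Atp2a2 fell by 1.66 ± 0.20 on the log2 scale, from 15626 ± 237 to 5451 ± 964 CPM (edgeR adjusted p = 1.9e-05), and Myh6 fell by 1.58 ± 0.28 (edgeR adjusted p = 0.000315). By the edgeR test 8553 of 14314 genes (59.8%) changed, 4404 up and 4149 down, with 1975 rises and 1349 falls over 1 on the log2 scale. With scaling by library size alone the median of all genes moved from 0.02 to 0.19 and the split became 5403 up and 3086 down.

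The largest rises at 8 weeks again included Sprr1a (9.06 ± 0.87), Derl3 (7.29 ± 0.80) and Serpina3n (6.82 ± 0.51), together with Chil1, a chitinase-like secreted protein, at 7.42 ± 0.62, Angptl7, a secreted angiopoietin-like protein, at 6.73 ± 0.45 and Comp, a matrix protein of cartilage and tendon, at 6.67 ± 0.47 on the log2 scale. Chil1 and Derl3 had 5 and 6 counts in the wild type libraries together, so the size of their changes rests on few counts. Comp rose from 4.83 ± 1.98 to 560.1 ± 88.3 CPM. The largest falls were those of Itgb6, an integrin subunit, from 20.8 ± 0.719 to 0.665 ± 0.504 CPM (-5.14 ± 0.31), Ky, a muscle protein needed for maintenance of muscle fibres, at -4.80 ± 0.22, Clcn1, a chloride channel, at -4.74 ± 0.50, Akap5, a scaffold of protein kinase A, at -4.60 ± 0.28, Kcnv2 at -4.52 ± 0.27 and Ces1d, a carboxylesterase of a gene family with similar members, at -4.45 ± 0.28. The highest edgeR adjusted p among these genes was 8.7e-06, for Derl3.

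Of 15 fetal and stress genes at 8 weeks 9 rose and 1 fell (camera adjusted p = 0.00462, adjusted p = 0.451 with an estimated correlation). Ccn2, a growth factor of connective tissue, rose 27.3-fold, and Acta1 did not pass, with 638 ± 542 CPM in homozygous and 629.8 ± 178 CPM in wild type hearts (edgeR adjusted p = 0.922). Of 20 calcium handling genes 12 fell and 3 rose (camera adjusted p = 0.0287, adjusted p = 0.451 with an estimated correlation). Hrc fell by 2.49 ± 0.28, Adrb1, the beta-1 adrenergic receptor, by 1.84 ± 0.18, and Sri, a calcium-binding partner of the ryanodine receptor, rose by 0.86 ± 0.09. Of 21 ion channel genes 17 fell and none rose, with a median of -1.29 (camera adjusted p = 1.41e-08, adjusted p = 0.243 with an estimated correlation). Scn4a, a sodium channel, fell by 3.29 ± 0.29 and Kcnj5, a potassium channel, by 1.29 ± 0.12. Of 22 sarcomere and Z-disc genes 10 fell and 4 rose (camera adjusted p = 0.0999), with Tnni3, cardiac troponin I, at -1.47 ± 0.18. For these 4 lists the counts adjusted over the list alone were equal.

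In energy metabolism at 8 weeks, 26 of 30 fatty acid oxidation genes fell and 2 rose, with a median of -1.19 (camera adjusted p = 3.19e-13, adjusted p = 0.382 with an estimated correlation). Acaa2, which catalyses the last step of beta-oxidation, fell by 2.07 ± 0.15 and Hadh by 1.76 ± 0.14. All 30 nuclear oxidative phosphorylation genes fell, with a median of -0.87 (camera adjusted p = 6.18e-12, adjusted p = 0.451 with an estimated correlation), and all 25 genes of the TCA cycle and branched-chain amino acids fell (camera adjusted p = 1.24e-10, adjusted p = 0.451 with an estimated correlation). Of 7 mitochondrially encoded genes 6 fell, and 7 adjusted over the list alone, while the list was not called (camera adjusted p = 0.114). The call of mt-Co1, a cytochrome oxidase subunit, ended when any 1 of 4 libraries was left out, wild type replicate 1 (adjusted p = 0.0647) or 2 (adjusted p = 0.0587) or homozygous replicate 3 (adjusted p = 0.0534) or 4 (adjusted p = 0.0589). Those of mt-Nd2 and mt-Nd4 each ended when any 1 of 5 libraries was left out (edgeR adjusted p up to 0.0673 and 0.0755). All mitochondrially encoded genes together, also those outside the 7 tested, took 10.8 ± 3.28% of counts in homozygous hearts, from 8.27% to 15.5%. In wild type hearts they took 15.7 ± 0.628%. Of 20 glycolysis genes 9 rose and 6 fell (camera adjusted p = 0.88), with Hk1, hexokinase, at 0.84 ± 0.09 and Eno3 at -1.92 ± 0.17. The other counts in this paragraph were equal when adjusted over the list alone.

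All 32 extracellular matrix genes rose at 8 weeks, with a median of 2.47 (camera adjusted p = 2.69e-19, adjusted p = 0.243 with an estimated correlation), among them Lox, which crosslinks collagen, at 37.4-fold and Bgn, biglycan, at 7.48-fold. Of 18 oxidative stress genes 15 rose and 1 fell (camera adjusted p = 3.91e-07, adjusted p = 0.243 with an estimated correlation), with the peroxidase Gpx3 at 3.10 ± 0.26 and Sod2 at -1.23 ± 0.16. Of 21 genes of autophagy, lysosome and ubiquitin ligases 12 rose and 4 fell, and adjusted over the list alone 14 rose and 5 fell (camera adjusted p = 0.00133, adjusted p = 0.243 with an estimated correlation). Bnip3, which takes part in removal of mitochondria, rose by 1.90 ± 0.15 and Sqstm1, the autophagy receptor p62, by 1.46 ± 0.13. Of 21 unfolded protein response genes 18 rose (camera adjusted p = 0.00138, adjusted p = 0.707 with an estimated correlation). Of 21 integrated stress response genes 17 rose and 2 fell (camera adjusted p = 0.00102, adjusted p = 0.474 with an estimated correlation), with Nupr1, a stress-induced nuclear protein, at 3.35 ± 0.22. Of 18 heat shock genes 3 rose and 5 fell (camera adjusted p = 0.496), among them Hspd1, the mitochondrial chaperonin, at -1.30 ± 0.13. Of 21 cytokine genes 14 rose and 1 fell, and adjusted over the list alone 15 rose and 2 fell (camera adjusted p = 0.000129, adjusted p = 0.451 with an estimated correlation), with Lcn2, lipocalin 2, at 23.7-fold. Of 25 cell cycle genes 3 fell and none rose (camera adjusted p = 0.827). Counts not given separately were equal when adjusted over the list alone.

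All 16 macrophage markers rose at 8 weeks, with a median of 2.20 (camera adjusted p = 6.97e-12, adjusted p = 0.243 with an estimated correlation), and Lgals3 rose 60.6-fold from 3.44 ± 0.355 to 240.01 ± 109 CPM. Of 12 fibroblast markers 10 rose (camera adjusted p = 8e-08, adjusted p = 0.243 with an estimated correlation), and of 11 activated fibroblast markers 9 rose (camera adjusted p = 0.000312, adjusted p = 0.408 with an estimated correlation). Of 12 endothelial markers 6 fell and 4 rose, and adjusted over the list alone 7 fell and 4 rose (camera adjusted p = 0.314). Kdr, the receptor of vascular endothelial growth factor, fell by 2.02 ± 0.14 and Emcn, endomucin, rose by 0.74 ± 0.17. Of 11 cardiomyocyte markers 6 fell and 2 rose (camera adjusted p = 0.0999), with Ckm at -2.30 ± 0.32, and of 11 smooth muscle markers 5 fell and 2 rose (camera adjusted p = 0.0522).

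In heterozygous hearts at 8 weeks, which carry 1 mutant copy, no single gene was called against wild type. Nppa stood at 702 ± 1016 CPM (SD, n = 4) against 249 ± 77.4 CPM (edgeR adjusted p = 1), with replicate 2 at 2224 CPM and the other 3 hearts between 116 and 249 CPM. Atp2a2 stood at 14480 ± 1961 CPM and Postn at 86.2 ± 43.9 CPM, with log2 changes of -0.08 ± 0.20 and 0.34 ± 0.29. The edgeR test called 0 of 14314 genes, with 326 at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0, with 348 and 801 genes at an unadjusted p under 0.05. Camera called 6 of 39 lists, with all adjusted p = 0.977 with an estimated correlation. They were heat shock genes at a median of -0.13 (camera adjusted p = 0.00181, with 1 of 18 lower adjusted over the list alone), the unfolded protein response at -0.13 (camera adjusted p = 0.0111), skeletal muscle genes at 0.82 (camera adjusted p = 0.0124), and mitochondrially encoded genes at 0.22, extracellular matrix at 0.11 and smooth muscle markers at -0.02 (camera adjusted p = 0.0413 for each). Each of these calls also ended without at least 1 single library. Without heterozygous replicate 2 the median of skeletal muscle genes was 0.28 (camera adjusted p = 0.561) and that of extracellular matrix -0.03 (camera adjusted p = 0.388), and without wild type replicate 2 that of heat shock proteins was 0.03 (camera adjusted p = 0.774). Without heterozygous replicate 3 the median of smooth muscle markers was 0.02 (camera adjusted p = 0.521). Homozygous and heterozygous hearts differed at 8864 genes, 4576 higher and 4288 lower in homozygous hearts, and at 5970 higher and 2934 lower with scaling by library size, under which the median of all genes moved from 0.02 to 0.22. There all 30 nuclear oxidative phosphorylation genes were lower (camera adjusted p = 2.98e-12, adjusted p = 0.426 with an estimated correlation). Of 32 matrix genes 31 were higher in homozygous hearts, and 32 adjusted over the list alone (camera adjusted p = 2.65e-19, adjusted p = 0.229 with an estimated correlation).

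**Figure D3:**
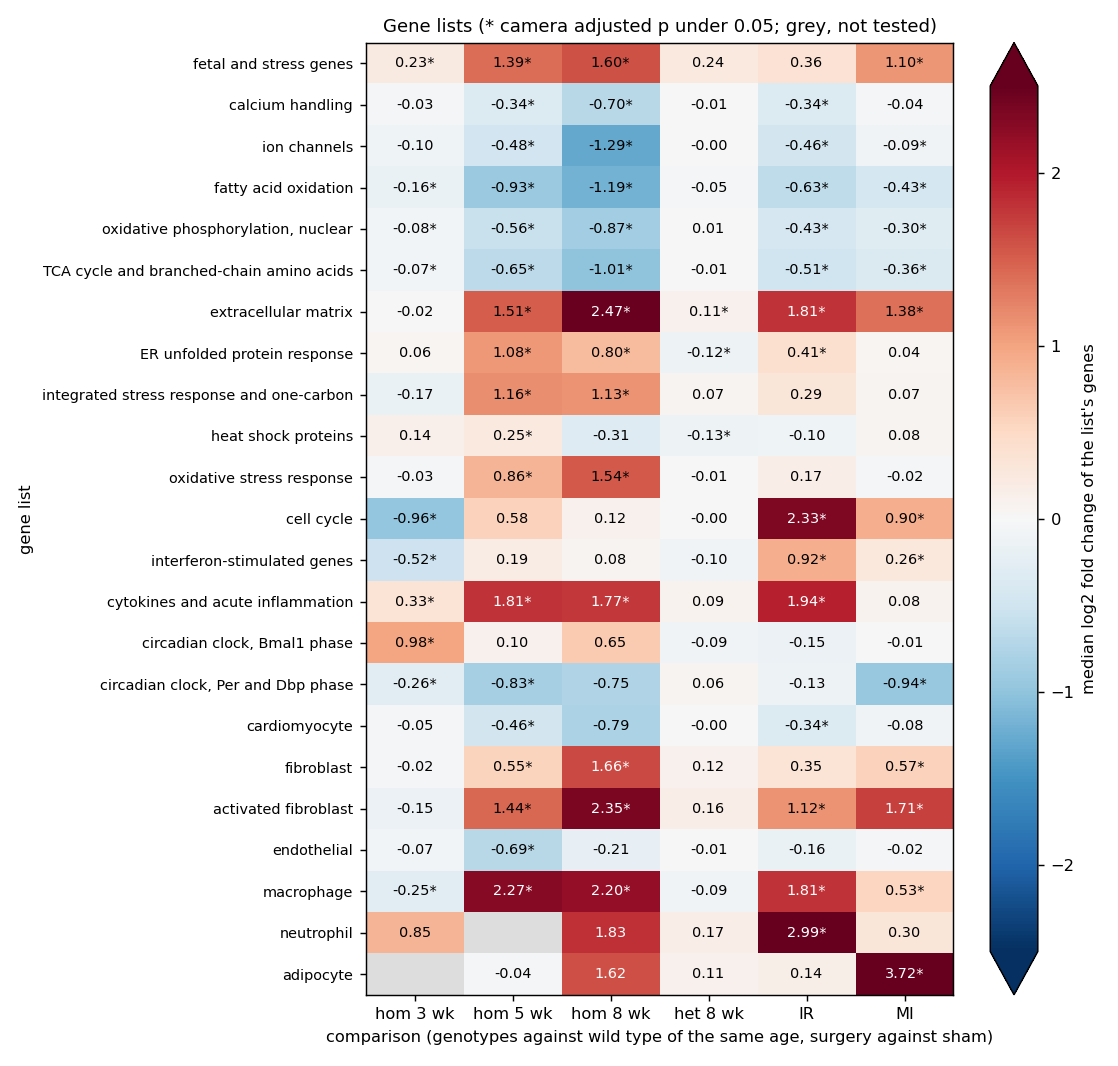
Median log2 fold change of each of 23 lists, some by function and some by cell type, in 6 comparisons. A star marks a camera adjusted p under 0.05, which with an estimated correlation held only for 6 lists at 5 weeks, and grey marks a list not tested. Extracellular matrix had medians of 1.51, 2.47, 1.81 and 1.38 in homozygous hearts at 5 and 8 weeks, after ischemia-reperfusion and after infarction.

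The change of the genotype effect between ages was tested over 14931 genes with all 39 libraries. Between 3 and 5 weeks the effect changed at 3042 genes, 1655 upward and 1387 downward. The log2 difference was 5.54 ± 0.96 for Spp1 (edgeR adjusted p = 8.54e-05), 4.77 ± 0.76 for Serpina3n and 4.63 ± 0.59 for Lgals3, and -3.21 ± 0.49 for Plekhh1, -2.77 ± 0.50 for Rab4a, a regulator of endosome recycling, and -2.41 ± 0.43 for Kcnv2. Of 16 macrophage markers 14 shifted upward, with a median of 2.36 (camera adjusted p = 5.91e-32, adjusted p = 0.00232 with an estimated correlation). Of 21 unfolded protein response genes 19 shifted upward, and 20 adjusted over the list alone (camera adjusted p = 5.82e-21, adjusted p = 0.0566 with an estimated correlation). Of 30 nuclear oxidative phosphorylation genes 24 shifted downward, and 28 adjusted over the list alone (camera adjusted p = 2.56e-13, adjusted p = 0.216 with an estimated correlation).

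Between 5 and 8 weeks the effect changed at 4218 genes, 2152 upward and 2066 downward. Angptl7, which stood at 2.31 CPM in homozygous and 2.10 CPM in wild type hearts at 5 weeks and at 324 CPM in homozygous hearts at 8 weeks, had a log2 difference of 6.82 ± 0.81 (SE, edgeR adjusted p = 1.51e-07). Comp had a difference of 5.42 ± 0.69, and A2m, the protease inhibitor alpha-2-macroglobulin, of 5.91 ± 1.17. Itgb6 had a difference of -5.13 ± 0.42 (edgeR adjusted p = 1.46e-10), as it stood at 21.6 and 18.5 CPM in homozygous and wild type hearts at 5 weeks, and Ky of -3.72 ± 0.44. Hspa1a and Hspa1b had differences of -4.56 ± 1.09 and -4.22 ± 1.14 that did not pass without wild type replicate 2 at 8 weeks (adjusted p = 0.109 and 0.54). Of 21 ion channel genes 14 shifted downward (camera adjusted p = 6.23e-06, adjusted p = 0.137 with an estimated correlation), and of 12 fibroblast markers 10 shifted upward and 1 downward (camera adjusted p = 6.23e-06, adjusted p = 0.137 with an estimated correlation), with equal counts adjusted over the list alone. Between 3 and 8 weeks the effect changed at 6965 genes, 3523 upward and 3442 downward, led by Angptl7 at 7.91 ± 0.61 and Comp at 7.45 ± 0.60. The 5-week libraries carry another style of library name than those of 3 and 8 weeks, and no wild type or homozygous heart of another age shares it, so that an effect of that set which differs between genotypes cannot be told apart from age.

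At 3 days after ischemia-reperfusion, remote myocardium showed more RNA of matrix, cell cycle, interferon, macrophage and neutrophil genes and less of mitochondrial and sarcomere genes. None of these list calls held with an estimated correlation (adjusted p from 0.107 to 0.312). Col1a1 rose 8.5-fold from 141 ± 66.9 to 1394 ± 635 CPM (SD, n = 4 each, edgeR adjusted p = 9.54e-06), Col3a1 by 2.43 ± 0.28 and Postn by 2.90 ± 0.41 on the log2 scale. Nppa rose by 1.37 ± 0.27 (edgeR adjusted p = 0.00145), a call that ended with all 39 libraries in the fit (adjusted p = 0.0739). Nppb rose by 0.88 ± 0.28 (edgeR adjusted p = 0.0261) and lost the call under 7 alternatives (adjusted p up to 0.137). Atp2a2 fell by 0.67 ± 0.15 and Myh6 by 0.91 ± 0.20. Myh7 did not pass, at 5262 ± 3551 CPM against 2506 ± 3973 CPM in sham (edgeR adjusted p = 0.439), where 12-week sham replicate 2 held 8452 CPM. Without that library the log2 change of Myh7 was 3.06 (edgeR adjusted p = 0.000622), and limma-voom with all libraries called it (adjusted p = 0.0363). By the edgeR test 4222 of 13611 genes changed, 2301 up and 1921 down, with 1006 rises and 65 falls over 1 on the log2 scale. With scaling by library size alone the median of all genes moved from -0.02 to 0.21 and the split became 4189 up and 431 down. Against the 12-week shams alone the count was 2174.

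The largest rises after ischemia-reperfusion included Spp1 at 126-fold (edgeR adjusted p = 7.23e-08), Sprr1a at 115-fold, Cd300lf, a receptor of myeloid cells, at 77.9-fold and Tnc, the matrix protein tenascin C, at 65.8-fold. Chil3, a chitinase-like protein of activated macrophages, stood at 13.4 ± 9.84 CPM with 1 count in the 4 sham libraries together, and Rgs1 at 5.13 ± 4.97 CPM with 2 counts there. Among the falls were Scn4b at -1.50 ± 0.22, Cytl1, a secreted protein, at -1.42 ± 0.25 and mt-Tm, a mitochondrial transfer RNA beside other mitochondrial genes, at -1.24 ± 0.19. Of 32 matrix genes 29 rose, and 30 adjusted over the list alone (camera adjusted p = 1.46e-29, adjusted p = 0.107 with an estimated correlation). Of 25 cell cycle genes 24 rose, with a median of 2.33 (camera adjusted p = 3.08e-25, adjusted p = 0.107 with an estimated correlation), among them the proliferation marker Mki67 at 6.74-fold and Top2a at 8.78-fold. Of 19 interferon-stimulated genes 15 rose, and 16 adjusted over the list alone (camera adjusted p = 9.91e-09, adjusted p = 0.203 with an estimated correlation), among them Isg15 at 3.47-fold. Of 22 cytokine genes 19 rose (camera adjusted p = 8.91e-11, adjusted p = 0.107 with an estimated correlation), and of 21 unfolded protein response genes 12 rose, and 13 adjusted over the list alone (camera adjusted p = 6.83e-06, adjusted p = 0.312 with an estimated correlation). Hmox1 rose 15.8-fold. Of 16 macrophage markers 15 rose (camera adjusted p = 1.15e-25, adjusted p = 0.107 with an estimated correlation), with Cd68 at 7.7-fold, and all 7 neutrophil markers rose (camera adjusted p = 3.31e-07, adjusted p = 0.107 with an estimated correlation), with Csf3r at 6.54-fold. Of 11 activated fibroblast markers 8 rose, and 10 adjusted over the list alone (camera adjusted p = 2.51e-07, adjusted p = 0.188 with an estimated correlation).

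On the falling side after ischemia-reperfusion, 27 of 30 nuclear oxidative phosphorylation genes fell, and 29 adjusted over the list alone (camera adjusted p = 7.77e-11, adjusted p = 0.312 with an estimated correlation). Of 30 fatty acid oxidation genes 20 fell, and adjusted over the list alone 25 fell and 1 rose (camera adjusted p = 4.38e-09, adjusted p = 0.312 with an estimated correlation), with Cpt2, a mitochondrial importer of fatty acids, at -0.86 ± 0.13. Of 25 genes of the TCA cycle and branched-chain amino acids 23 fell by either count (camera adjusted p = 3.92e-13, adjusted p = 0.188 with an estimated correlation), and of 8 mitochondrially encoded genes 7 fell by either count (camera adjusted p = 0.000968, adjusted p = 0.312 with an estimated correlation). All mitochondrially encoded genes together, also those outside the 8 tested, took 19.6 ± 1.27% of counts against 24.4 ± 1.49% in sham. Of 22 sarcomere genes 15 fell, and 16 adjusted over the list alone (camera adjusted p = 6.83e-06, adjusted p = 0.188 with an estimated correlation), with the giant protein titin, Ttn, at -0.51 ± 0.09. Of 21 ion channel genes 10 fell, and 12 adjusted over the list alone (camera adjusted p = 0.000108, adjusted p = 0.107 with an estimated correlation). Of 20 calcium handling genes 11 fell and 2 rose by either count (camera adjusted p = 0.00975, adjusted p = 0.312 with an estimated correlation). Of 11 cardiomyocyte markers 6 fell, and 7 adjusted over the list alone (camera adjusted p = 0.00313, adjusted p = 0.264 with an estimated correlation), and of 12 endothelial markers 3 fell (camera adjusted p = 0.133).

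At 8 weeks after infarction, remote myocardium showed more RNA of natriuretic peptides, matrix and activated fibroblast genes. The calls of the matrix and activated fibroblast lists were lost with an estimated correlation (adjusted p = 0.0998 for each). Nppa rose 12.4-fold from 221 ± 82.0 to 2971 ± 1258 CPM (SD, n = 4 each, edgeR adjusted p = 2.85e-05), and Postn rose 6.98-fold from 62.1 ± 25.3 to 473 ± 232 CPM (edgeR adjusted p = 0.000761). Acta1 rose by 1.80 ± 0.36 and Nppb by 1.34 ± 0.28 on the log2 scale, the latter without a call against the 20-week shams alone (adjusted p = 0.0681). Col1a1 passed with 1.04 ± 0.31 (edgeR adjusted p = 0.0429) and lost the call under 7 alternatives (adjusted p up to 0.137), and Col3a1 (0.85 ± 0.27), Atp2a2 (-0.30 ± 0.15) and Myh7 (0.29 ± 0.79) did not pass. The result for Myh7 rests on 12-week sham replicate 2, without which the log2 change was 2.47 (edgeR adjusted p = 0.0113). By the edgeR test 1550 of 13611 genes changed, 901 up and 649 down, with 328 rises and 75 falls over 1 on the log2 scale. With scaling by library size alone the median of all genes shifted by 0.11 and the split became 1406 up and 317 down. The count was 663 without infarct replicate 2, 957 without infarct replicate 1, 789 without 20-week sham replicate 1 and 853 against the 20-week shams alone.

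Rises after infarction included Sprr1a at 4.27 ± 0.59 (edgeR adjusted p = 0.000586) and Comp at 4.09 ± 0.41 (edgeR adjusted p = 7.35e-05). Falls included Ppbp, a platelet chemokine, at -2.58 ± 0.58, Snai3 at -1.91 ± 0.43, Lrrc4b at -1.73 ± 0.26 and Ces1d at -1.50 ± 0.22. Of 14 fetal and stress genes 8 rose by either count (camera adjusted p = 3.38e-10, adjusted p = 0.0998 with an estimated correlation), among them Xirp2, an actin-binding protein of the intercalated disc, at 0.92 ± 0.16. Of 32 matrix genes 29 rose, and 32 adjusted over the list alone (camera adjusted p = 1.01e-42, adjusted p = 0.0998 with an estimated correlation), with Col12a1 at 10.7-fold and Thbs4, thrombospondin 4, at 9.7-fold. Of 12 fibroblast markers 9 rose, and adjusted over the list alone 11 rose and 1 fell (camera adjusted p = 2.8e-08, adjusted p = 0.153 with an estimated correlation). Of 11 activated fibroblast markers 7 rose, and 9 adjusted over the list alone (camera adjusted p = 5.11e-16, adjusted p = 0.0998 with an estimated correlation), with Cilp, an intermediate layer protein of cartilage, at 8.81-fold. Of 25 cell cycle genes 7 rose and 1 fell, and adjusted over the list alone 19 rose and 1 fell (camera adjusted p = 2.93e-08, adjusted p = 0.416 with an estimated correlation). Nox4, an NADPH oxidase, rose 5.78-fold. Of 16 macrophage markers 3 rose, and 10 adjusted over the list alone (camera adjusted p = 8.37e-06, adjusted p = 0.416 with an estimated correlation).

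Of 30 fatty acid oxidation genes 11 fell after infarction, and 20 adjusted over the list alone (camera adjusted p = 1.33e-09, adjusted p = 0.416 with an estimated correlation), and of 30 nuclear oxidative phosphorylation genes 9 fell, and 25 adjusted over the list alone (camera adjusted p = 1.71e-11, adjusted p = 0.416 with an estimated correlation). Of 25 genes of the TCA cycle and branched-chain amino acids 15 fell, and 21 adjusted over the list alone (camera adjusted p = 3.94e-14, adjusted p = 0.248 with an estimated correlation), with Ppm1k, the phosphatase that activates branched-chain amino acid breakdown, at -0.85 ± 0.15. Mitochondrially encoded genes, none of 8 past the test singly, had a median of -0.28 (camera adjusted p = 0.0194, adjusted p = 0.635 with an estimated correlation). All mitochondrially encoded genes together, also those outside the 8 tested, took 21 ± 2.14% of counts. Of 21 ion channel genes, with a median of -0.09 that turned to 0.02 with scaling by library size, 5 fell by either count (camera adjusted p = 0.0024, adjusted p = 0.248 with an estimated correlation), among them Kcnip2 at -0.81 ± 0.11 and Kcnd2, a pore subunit of the transient outward current, at -1.19 ± 0.18. Of 20 calcium handling genes 3 fell and 1 rose, and adjusted over the list alone 3 fell and 2 rose (camera adjusted p = 0.62).

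The comparison of mutant with ischemic hearts was made across genes, which are not independent replicates. Homozygous hearts at 8 weeks and infarcted hearts shared 703 rising genes, where independent lists would share 270, and 505 falling genes, where they would share 194, and 52 genes moved in opposite directions, where 464 would. The fold changes of 13493 genes correlated with r = 0.546 (Spearman 0.501). With ischemia-reperfusion the homozygous hearts at 8 weeks shared 1572 rising genes (684 for independent lists) and 1414 falling genes (578), with 152 in opposite directions (1261) and r = 0.566 (Spearman 0.585). At 5 weeks r was 0.721 with ischemia-reperfusion and 0.543 with infarction. The 5- and 8-week effects had r = 0.706, with 2145 rising genes (894 for independent lists) and 1973 falling genes (865) in both. The 3-week effect had r = 0.107 with the 5-week effect, and -0.043 without homozygous replicate 3 at 3 weeks.

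**Figure D4:**
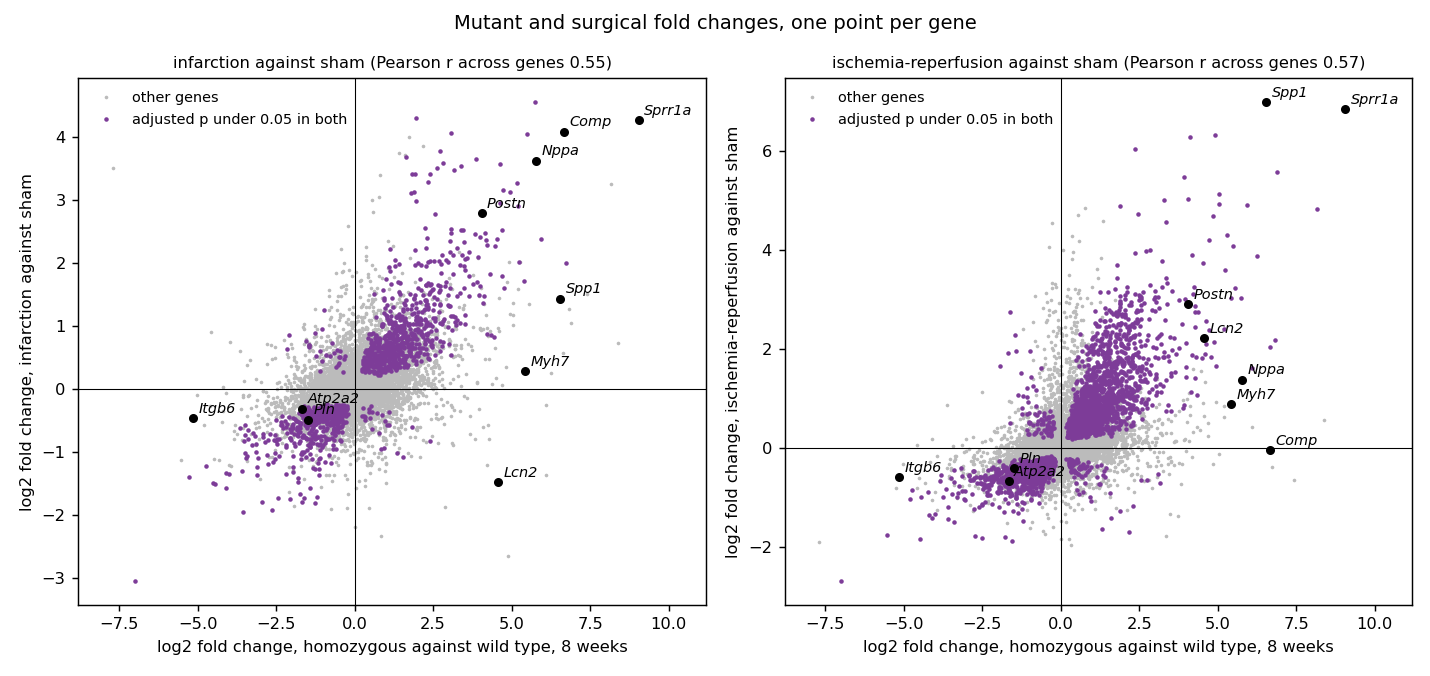
Log2 fold change of each gene in homozygous hearts at 8 weeks, plotted against that after infarction and after ischemia-reperfusion, 1 point per gene. Pearson's r across genes was 0.546 for infarction and 0.566 for ischemia-reperfusion.

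The surgery comparisons share their sham hearts. Between them 536 genes rose in both (152 for independent lists) and 14 moved in opposite directions (237), with r = 0.565. Unchanged groups simulated against the same shams gave r = 0.519, and a covariance of 0.0242 against 0.1856 observed, a difference of 0.1614. With ischemia-reperfusion set against the 12-week and infarction against the 20-week shams, 253 genes rose in both (54 for independent lists), 134 fell in both (17), 2 moved in opposite directions (61), r was 0.387 and the covariance 0.1914. With the shams exchanged, 140 genes rose in both (49), 66 fell in both (20), 15 moved in opposite directions (63), r was 0.26 and the covariance 0.1369. The heterozygous and homozygous effects at 8 weeks share 3 wild type hearts. Their r was 0.267, and 0.049 without heterozygous replicate 2, and their covariance was 0.0814 against 0.0346 in simulated unchanged groups. Those simulated groups had r = 0.583. Real changes widen the spread of fold changes and unchanged groups lack them, so for neither pair of comparisons can the simulated r be set against the observed one.

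The effect of the homozygous genotype at 8 weeks differed from that of infarction at 5580 of 14931 genes, 2932 with a higher and 2648 with a lower effect in the mutant. Oxidative stress genes had a higher effect in the mutant for 15 of 18 genes and a lower one for 1 by either count, with a median difference of 1.39 (camera adjusted p = 1.01e-08, adjusted p = 0.00703 with an estimated correlation). Lcn2 differed by 6.06 ± 0.69 (SE, edgeR adjusted p = 3.98e-08) and Tmem252, with 4 counts in wild type hearts together, by 7.47 ± 1.09. Itgb6 differed by -4.66 ± 0.42, Mycn, a transcription factor, by -4.68 ± 0.55 and Akap5 by -4.30 ± 0.55. Of 21 ion channel genes 17 had a lower effect in the mutant by either count (camera adjusted p = 1.01e-08, adjusted p = 0.0569 with an estimated correlation), and of 21 unfolded protein response genes 17 had a higher one, and 18 adjusted over the list alone (camera adjusted p = 1.07e-06, adjusted p = 0.444 with an estimated correlation). Against ischemia-reperfusion the effect differed at 5052 genes, 2485 higher and 2567 lower in the mutant. Chil1, with 5 counts in wild type hearts together, differed by 8.07 ± 0.87 and Comp by 6.75 ± 0.58, and Apln, the peptide apelin, by -4.25 ± 0.50. Of 25 cell cycle genes 22 had a lower effect in the mutant by either count, with a median of -2.22 (camera adjusted p = 5.84e-09, adjusted p = 0.497 with an estimated correlation), and of 12 fibroblast markers 10 had a higher and 1 a lower effect, and adjusted over the list alone 10 and 2 (camera adjusted p = 1.4e-08, adjusted p = 0.0525 with an estimated correlation). Age and the source of the control hearts also differ between the mutant and the surgery sets.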

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

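The tests of heterozygous replicate 2, of cell composition and of Myh7 in the sham heart were chosen only after the results were seen, and the skeletal muscle genes of single libraries were looked up only after their Nppa was seen. Those of scaling and of other splits were chosen before. Single libraries were listed where they stood far from the other libraries of their group by Dixon's test, and effects where a test of their difference passed. Dixon's test was run on the CPM of the marker genes, the total count and the mitochondrial share within each group. It listed a library in 16 of 108 such tests, where 1 in 20 would give 5.4. The tests share libraries and the CPM were not on a log scale, so 5.4 is no firm expectation of chance.

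Heterozygous replicate 2 at 8 weeks stood apart in 7 marker genes, with Nppa at 2224 CPM (next library 248.7), Nppb at 353 CPM (124.8), Myh7 at 308 CPM (75.47), Acta1 at 1880 CPM (485.8), Col1a1 at 348 CPM (217.9), Col3a1 at 675 CPM (378.9) and Pln at 4010 CPM (5186). RNA of a homozygous heart mixed in at the share that Nppa shows would raise all genes by that share. Yet at least 65.5% of the 87 genes raised 8-fold or more had an implied share under 0.5 times that of Nppa. The implied share was 13.3% for Nppa, chosen after it stood apart, and had a median of 3.83% over the genes. A smaller share mixed in beside a rise of Nppa in this heart was not tested. A homozygous heart under a heterozygous label is argued against by 0% of those genes lying in the range of homozygous libraries, and atrial tissue by a median log2 difference of -0.71 over 6 atrial markers. Atp2a1, the calcium pump of fast skeletal muscle, stood at 20.3 CPM here against 1.02 to 1.17 CPM in the other heterozygous hearts, and Mylpf, a light chain of fast skeletal myosin, at 4.11 CPM against 0.828 to 1.33 CPM. A difference of this single animal stays open and was not tested, nor was skeletal muscle in the sample.

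Genes of oxidative metabolism fell in homozygous hearts at 5 and 8 weeks, with list calls that, apart from fatty acid oxidation at 5 weeks (adjusted p = 0.045), were lost with an estimated correlation (adjusted p = 0.174 at 5 weeks and 0.451 at 8 weeks for nuclear oxidative phosphorylation). A loss of cardiomyocytes alone would raise markers of the other cell types alike, but macrophage and endothelial markers moved apart by 2.83 at 5 weeks and 2.59 at 8 weeks on the log2 scale. A gain of macrophages would also lower the share of cardiomyocytes and move these markers apart. The test therefore cannot decide on a lower share of cardiomyocytes that comes about in that way. At 8 weeks the scaling of the libraries is argued against by a median of -0.72 for nuclear oxidative phosphorylation genes under the alternative scaling that moved it most. This test was not run at 5 weeks, where library size scaling gave a median of 0.206 over all genes. An effect of the genotype stays open as a hypothesis, as does a change within the cell types that rose.

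Myh7 stood at 8452 CPM in 12-week sham replicate 2, where the next sham held 876.8 CPM. A heart after ischemia-reperfusion under a sham label is argued against, as 4.55% of 22 genes raised 8-fold or more by that surgery lay in its range in this library. Reads of Myh6 counted for Myh7 would give a like ratio of the 2 genes in all libraries, but the ratio here was 1680 times the lowest one. A difference of this single animal stays open and was not tested.

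Other single libraries stood far from their group. Homozygous replicate 3 at 3 weeks held Nppa at 1621 CPM (next 245.6), Nppb at 327 CPM (65.08) and Acta1 at 891 CPM (208.5), with Atp2a1 at 9.15 CPM (0.979) and Mylpf at 5.34 CPM (1.47). Wild type replicate 1 at 5 weeks held Nppa at 288 CPM (189.7). Homozygous replicate 3 at 5 weeks had 15.9% of counts in mitochondrially encoded genes (14.7). Homozygous replicate 1 at 8 weeks held Atp2a2 at 6882 CPM (5172). Its pairs with the other homozygous hearts had chi-square statistics per gene from 57.3 to 97.4, against 21.9 to 50.6 among those hearts. Not listed by Dixon's test, it also held 15.5% of counts in mitochondrially encoded genes (10.6), while its Nppa lay within the range of the others. Ischemia-reperfusion replicate 4 held Nppb at 280 CPM (521.7), and infarct replicate 2 held Acta1 at 2104 CPM (1147).

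The effect of the homozygous genotype differed between 5 and 3 weeks at 3042 genes, between 8 and 5 weeks at 4218 and between 8 and 3 weeks at 6965. Between 8 and 5 weeks, differences on the log2 scale by edgeR were 6.82 for Angptl7 (adjusted p = 1.51e-07), 5.91 for A2m (adjusted p = 0.000243), 5.82 for Mpzl2 (adjusted p = 0.000497), 5.42 for Serpina3m (adjusted p = 0.0333) and 5.42 for Comp (adjusted p = 4.21e-07). They were -5.13 for Itgb6 (adjusted p = 1.46e-10), -4.56 for Hspa1a (adjusted p = 0.00185), -4.22 for Hspa1b (adjusted p = 0.00513), -3.97 for Arc (adjusted p = 0.00154) and -3.72 for Ky (adjusted p = 1.4e-07). Mpzl2 had 3 counts in homozygous hearts at 5 weeks together. Serpina3m lost the call under 4 alternatives (adjusted p up to 0.881), among them the fit of the groups in the contrast alone and those without wild type replicate 3 at 5 weeks or wild type replicate 1 or 3 at 8 weeks. Hspa1a and Hspa1b lost the call without wild type replicate 2 at 8 weeks, with adjusted p = 0.109 and 0.54.

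The homozygous effect at 8 weeks differed from that of infarction at 5580 genes and from that of ischemia-reperfusion at 5052. Against infarction the log2 differences by edgeR were 7.47 for Tmem252 (adjusted p = 1.8e-06), 6.82 for Derl3 (adjusted p = 0.000586), 6.35 for Rpph1 (adjusted p = 2.88e-07), 6.08 for Jaml (adjusted p = 0.000397) and 6.06 for Lcn2 (adjusted p = 3.98e-08). They were -4.68 for Mycn (adjusted p = 6.52e-08), -4.66 for Itgb6 (adjusted p = 1.07e-09), -4.30 for Akap5 (adjusted p = 2.46e-07) and -4.21 for Prnd (adjusted p = 8.44e-06). Tmem252, Derl3, Rpph1 and Jaml had 4, 6, 12 and 11 counts in wild type hearts at 8 weeks, so the size of their differences rests on few counts. The fitted -11.12 for Alb (adjusted p = 0.00111) rests on 1 count in homozygous hearts and is no bound, and limma-voom did not call it (adjusted p = 0.272).

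Of 35 splits of the same libraries, the real one called the most genes for homozygous hearts at 5 weeks (5821, highest other 0). The same held at 8 weeks (7792 in a fit of these 2 groups, highest other 3884, with homozygous replicate 1 beside the wild type hearts). It also held against heterozygous hearts (8291, highest other 0), for ischemia-reperfusion (3683, highest other 0) and for infarction (1393, highest other 2). A share of 1 in 35 is the lowest that these splits can give, so they argue against chance in each comparison but cannot exclude it. For homozygous hearts at 3 weeks (0, highest other 1) and for heterozygous hearts (0, highest other 8) they cannot decide, as all 35 splits call at least 0 genes. For differences between effects, a drawn split can keep or reverse the real groups in 1 of the 2 comparisons, so these splits do not decide on chance. The counts were 3343 between 5 and 3 weeks (highest other 3206), 3963 between 8 and 5 weeks (6805), 6166 between 8 and 3 weeks (6388), 4707 from infarction (6852) and 3888 from ischemia-reperfusion (6379).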

How the results depend on the processing

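The alternative without mitochondrially encoded genes was chosen only after the data were seen, and all others before. Where at least 1 of the 2 values was called, no named gene turned direction, but 7 list medians did. Turns of direction without a call were not counted. With scaling by library size the median of ion channels turned from -0.088 to 0.021 after infarction, and that of autophagy from -0.017 to 0.189 at 5 weeks. In heterozygous hearts, leaving out each library gave -0.034 to 0.197 for extracellular matrix, -0.182 to 0.033 for heat shock proteins, -0.059 to 0.019 for smooth muscle, -0.36 to 0.665 for erythroid and -0.387 to 0.492 for adipocyte markers. Of 466 named gene results 80 lost the call under at least 1 alternative, of 50 named differences 8, and of 269 list results 102. The totals for named genes and lists include results without a call, which cannot lose one. Among these list results, every call but 6 at 5 weeks was lost with an estimated correlation. At 3 weeks the count of 0 became 112 with DESeq2, 25 without a filter and 40 with all 39 libraries in the fit, and 0 to 4 with each library left out. With a fold change over 1 on the log2 scale required, the counts were 1201 at 5 weeks, 3324 at 8 weeks, 3268 for homozygous against heterozygous, 1071 for ischemia-reperfusion and 403 for infarction, as that choice removes genes. Against age-matched shams alone, with fewer libraries, they were 2174 for ischemia-reperfusion and 853 for infarction. Leaving out each library gave 663 to 1570 for infarction (1550 with all), with 663 without infarct replicate 2, 957 without infarct replicate 1 and 789 without 20-week sham replicate 1. The correlation of the homozygous effect at 8 weeks with ischemia-reperfusion was 0.636 over genes of at least 5 CPM. The cause was not tested for the other moves. Without mitochondrially encoded genes the counts were 0, 5800 and 8560 for homozygous hearts at 3, 5 and 8 weeks, 4312 for ischemia-reperfusion and 1542 for infarction. The covariate for sex was not run, as 39 of 39 libraries stood on the male side.

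Groups share replicate numbers in the labels. Deviations of same-numbered libraries correlated from -0.059 to 0.233 at 3 weeks, from 0.007 to 0.1 at 5 weeks, from -0.096 to 0.062 at 8 weeks, from -0.159 to 0.159 for ischemia-reperfusion (1 of 4 pairs over 0.1) and from -0.025 to 0.07 for infarction, so the numbers do not pair the samples. With the replicate block the counts were 0, 5901 and 7566 for homozygous hearts at 3, 5 and 8 weeks, 0 for heterozygous hearts, 7851 for homozygous against heterozygous, 1751 for ischemia-reperfusion (74.1% of them up) and 1182 for infarction. For differences the block gave 3101 between 5 and 3 weeks, 4551 between 8 and 5, 5904 between 8 and 3, 3303 from infarction and 2713 from ischemia-reperfusion. A library without a same-numbered one in the other group adds nothing to a blocked comparison. The shams carry only numbers 1 and 2, so this held for replicates 3 and 4 of both surgeries. At 8 weeks it held for homozygous and heterozygous replicate 4 against wild type. The blocked counts for those comparisons thus rest on fewer libraries.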

Other observations

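The lists below were written before the data were examined. Single genes of the circadian clock changed in homozygous hearts, while no call of a clock list there held with an estimated correlation. At 5 weeks 7 of 10 genes of the Per and Dbp phase fell, and 8 adjusted over the list alone (camera adjusted p = 0.00227, adjusted p = 0.33 with an estimated correlation), among them the clock output factor Hlf by 1.46 ± 0.19 on the log2 scale and the repressor Nr1d1 by 0.78 ± 0.12. At 8 weeks 6 fell and 1 rose, and adjusted over the list alone 7 fell and 1 rose (camera adjusted p = 0.0591), with Dbp at -2.04 ± 0.27 and Per1 at 1.39 ± 0.31, while 4 of 6 genes of the Bmal1 phase rose (camera adjusted p = 0.267), with Arntl at 28.8 CPM against 9.29 CPM in wild type hearts. The hour of collection is not given in the labels used here. Of 14 genes of renin-angiotensin and adrenergic signalling 2 rose and 8 fell at 5 weeks (camera adjusted p = 0.097), and 5 rose and 4 fell at 8 weeks, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.936), where Ace, the angiotensin-converting enzyme, rose by 2.30 ± 0.17 and Adra1a, an alpha-1 adrenergic receptor, fell by 2.91 ± 0.26. Of 16 immediate early genes 11 rose and 1 fell at 5 weeks, and adjusted over the list alone 11 rose and 2 fell (camera adjusted p = 9.18e-05, adjusted p = 0.174 with an estimated correlation), with the stress factor Atf3 at 2.38 ± 0.16. After infarction none of 16 passed, with a median of -0.88 (camera adjusted p = 0.00154, adjusted p = 0.712 with an estimated correlation).

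Markers of rarer cell types also moved. At 8 weeks 5 of 6 mesothelial and epicardial markers rose in homozygous hearts (camera adjusted p = 0.0421, adjusted p = 0.451 with an estimated correlation), with Msln, mesothelin, at 4.84 ± 0.63 and Upk3b at 3.05 ± 0.48. After infarction 4 of 5 adipocyte markers rose, and 5 adjusted over the list alone (camera adjusted p = 0.00148, adjusted p = 0.416 with an estimated correlation), with the fat hormone Adipoq at 7.70 ± 5.27 CPM against 0.354 CPM in sham, a call that limma-voom did not make (adjusted p = 0.0658). Cidec lost the call under 3 alternatives and Plin1 under 7 (adjusted p up to 0.197 and 0.214). Of 6 B cell markers 2 rose after infarction, and 4 adjusted over the list alone (camera adjusted p = 0.00139, adjusted p = 0.416 with an estimated correlation). All 5 erythroid markers fell at 5 weeks (camera adjusted p = 0.13), of which Alas2, Hbb-bt and Hbb-bs lost the call with all 39 libraries in the fit, and the latter 2 also with DESeq2 (adjusted p up to 0.169).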
